A study of Homo sapiens with 30 samples.

How the data were processed

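RNA was measured in 30 libraries of the H7 human embryonic stem cell line and of its derivatives during directed differentiation to cardiomyocytes. The labels give 15 groups of 2 libraries each: 11 time points (22 libraries) and 4 sorted populations (8 libraries). Per the labels' protocols, cells were treated with 12 µM of the GSK3 inhibitor CHIR99021 for 24 hours and later with 5 µM of the WNT inhibitor IWP4 for 2 days. Cardiomyocytes of day 31 were purified on Percoll. PMESO cells were sorted on day 3 as positive for the receptor ROR2, with the ROR2-negative cells as their counterpart. CMESO cells were sorted on day 4 as positive for ROR2 and PDGFRa, with ROR2-positive, PDGFRa-negative cells as their counterpart. Libraries were made from 500 ng of total RNA depleted of ribosomal RNA with 10 PCR cycles, and were sequenced as read pairs of 100 nt.

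The authors deposited 3 tables. The time-course table holds FPKM values, 1 per gene and time point, so the 2 libraries of a time point are not given apart; the header names only the time points, and the unit was taken from the pipeline in the submitters' processing notes and from the values. These notes name TopHat2 2.0.8b, Bowtie2 2.1.0.0, Cufflinks (without a version) and the human genome build hg19. The gene annotation, the strand setting and any scaling between time points are not given in the sources used here. Each of the 2 sort tables holds, per the file headers, the authors' FPKM value of each gene in the negative and in the positive population. Per the file headers these tables also hold the authors' log2 of the fold change, the linear ratio, the test statistic (a score), the p-value and the q-value. Both tables hold only genes with a q-value under 0.05 in the deposited form used here: the largest q-values are 0.0497 for the D3 sort and 0.0499 for the D4 sort. From the ratio of q-value to p-value by rank, the authors' adjustment ran over 16013 to 16649 genes at D3 and 11592 to 13305 at D4, so a gene missing from a sort table cannot be read as equal between the populations. Coordinates of the sort tables were turned to 1-based, because 1921 loci of the D3 table have the length of a GENCODE 29 gene if the start counts from 0 and 59 if it counts from 1.

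The time-course table has 41495 entries, of which 6441 are listed at 0 throughout. Genes with at least 1 FPKM in at least 1 time point were kept (21715). The plan made before the data were examined asked for at least 1 in at least 2 libraries, and a column stands for 2 libraries. Gene types came from GENCODE 29 by gene name. Of the kept genes 76.5% (16621) had a match, 14546 of them protein-coding, and a spreadsheet had turned 27 names in the table into dates. That annotation belongs to another genome build, so it served for gene type, gene length and exon overlap, and no coordinate of it is printed.

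The planned tests (limma on log2 values per library, and camera for gene lists) need the libraries apart and were not run. As the plan laid down for that case, time-course comparisons are values without a test: a gene was counted as higher or lower when log2(FPKM + 1) differed by at least 1 (2-fold). Fold changes on that scale understate the change of genes with low values. Where an abundant gene is listed at exactly 0, the value can be a failed estimate, and no fold is given. A list of genes was described by the number of its members 2-fold higher or lower, by the median log2 change of its measured members, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. For the sorts, the authors' calls (q-value under 0.05) were used; counts of 2-fold genes also needed at least 1 FPKM in 1 population and a difference of at least 1 in log2(FPKM + 1). The direction of a list's called members was compared with that of all other called genes by a two-sided Fisher's exact test, for lists with at least 5 called members, with Benjamini-Hochberg adjustment over the lists tested. Genes are not independent replicates, which makes these p-values too small. The labels do not say whether the 2 libraries of a group came from separate cultures, so the authors' p-values may measure technical spread. The sort tables were normalized apart from the time course.

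Before the data were examined, 23 gene lists were fixed: pluripotency, primitive streak and mesendoderm, cardiac mesoderm and progenitor, sarcomere, calcium handling and ion channels, mitochondrial and fatty acid metabolism, proliferation, WNT target genes, DNA methylation machinery, Polycomb, epithelial-mesenchymal transition, paraxial mesoderm, definitive endoderm and liver, neural, endothelial, smooth muscle and fibroblast, epicardial, blood, skeletal muscle, HOX genes, imprinted genes, dissociation and immediate early genes, and RNA composition. The rule for named genes, also fixed then, takes the 10 largest increases and decreases between stem cells and cardiomyocytes and in each sort, the 3 largest of each step between time points, members of the lists, and the sort markers, among genes of at least 5 FPKM in 1 group. Many genes the rule named for the steps jump up and down between neighbouring columns. In all, 152 genes were set apart as jumping. They have at least 20 FPKM and at least 3 opposite jumps of at least 3 on the log2 scale, or belong to the 35 alternating genes described at the end. The largest protein-coding genes without such jumps are therefore named too, a choice made after their values were seen.

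No read counts were used. In short single-exon genes the lowest FPKM values, multiplied by gene length, fall in steps, which gives an approximate depth. The worth of 1 fragment in a gene of 1 kb ran from 0.02425 FPKM at D2 to 0.04775 FPKM at D15. Depth relative to D1 was 0.625 in stem cells, 0.599 at D5, 0.524 at D15 and 0.763 in cardiomyocytes, and 0.781 to 1.03 at the other time points, so low values are least precise at D15, D5 and in stem cells. Gene lengths came from another annotation, and the steps are not whole reads for all genes. The D15 estimate rests on 87 genes, those of the other time points on 222 (hESC) to 350 (D6).

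Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, and rescaling by median-of-ratios factors (0.972 to 1.07). Others were added afterwards: protein-coding genes only, genes above 0 in both columns only, leaving out genes that alternate between columns, other start and end points, leaving the sort marker out of its list, a limit on the authors' ratio, and another limit on the fold or the q-value. For the comparison of cardiomyocytes with stem cells, data were simulated from the stem cell column with a small noise set by hand. Of 21715 genes, 200 of at least 5 FPKM were changed 4-fold. All 200 were counted and 0 unchanged genes were. With so small a noise this outcome was close to fixed, so it checks the counting and gives no error rate for the real counts. Of 100 random lists, 7 lay outside the middle 95% of the matched lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.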

Results

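Gene expression was profiled by RNA sequencing while H7 human embryonic stem cells (hESC) were turned into cardiomyocytes by activating and then blocking WNT signalling. The series covers 11 time points, from hESC through days 1, 2, 3, 4, 5, 6, 8, 10 and 15 (D1 to D15) to purified cardiomyocytes of day 31, with 2 libraries at each. It also covers 2 sorts, of D3 cells by the receptor ROR2 and of ROR2-positive D4 cells by the receptor PDGFRa, with 2 libraries per population. The tables used here give 1 FPKM value per gene and group, so no spread between libraries can be set beside any time-course value, and differences over time are reported as higher or lower without a test. The summed FPKM was highest in hESC (1429860) and lowest at D15 (617580). Protein-coding genes held from 43.0% of it in hESC to 76.0% at D1, and small RNAs held 37.5% in hESC, 38.8% at D5 and 12.0% at D1. Since FPKM divides by gene length, short RNAs weigh more in these shares, which are not shares of reads or of RNA mass. Each time point had 14937 (D2) to 17927 (D15) genes at 1 FPKM or more. The highest and lowest time points lay at least 2-fold apart for 18390 of the 21715 genes kept, and for 11868 when hESC, D15 and cardiomyocytes were left out.

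To see what separates the ends of the differentiation, cardiomyocytes were compared with hESC. Contractile genes led the increases. MYH6, the alpha heavy chain of cardiac myosin, stood at 0.577 FPKM in hESC and 2123 in cardiomyocytes, and the atrial light chains MYL4 (0.747 against 1298) and MYL7 (4.58 against 3792), the troponins TNNT2 (2785 in cardiomyocytes) and TNNI1 (1.16 against 1038) and PLN, the inhibitor of the calcium pump of the sarcoplasmic reticulum (0.311 against 717), were next among protein-coding genes. The largest decreases were in genes of the pluripotent state: POU5F1 stood at 1026 FPKM in hESC and 1.54 in cardiomyocytes, DPPA4 at 714 and 0.789, LIN28A, a blocker of let-7 microRNA processing, at 708 and 1.49, and TDGF1, a co-receptor of NODAL, at 346 and 0.993. Besides these, the 10 largest increases held the imprinted noncoding RNA H19 (3.15 against 1772), SNORA79, AC132217.4 and CTD-2545M3.8, and the 10 largest decreases held MIR302B (2054 against 4.68), SNORA57, SNORA71D, RP11-256I9.2, RP11-267L5.1 and CTB-151G24.1. SNORA79 and SNORA57 jump back and forth between columns, so their differences are uncertain. In all, 4057 genes were at least 2-fold higher and 3663 at least 2-fold lower in cardiomyocytes among the 21715 kept, and among protein-coding genes these counts were 2785 and 2740 of 14546. The balance turned after rescaling (3815 higher, 3879 lower) and with D10 in place of cardiomyocytes (2906 and 2969). Across protein-coding genes, which are not independent replicates, the log2 values of the ends had a Pearson r of 0.750.

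Heart muscle lists were higher in the same comparison. Of 27 measured sarcomere genes, 25 were 2-fold higher in cardiomyocytes (median log2 change 6.95), among them ACTC1 (5.28 against 2202 FPKM) and MYBPC3 (0.104 against 251). TNNI3, the adult cardiac troponin I, was measured at 82.5 FPKM in hESC and 52.7 in cardiomyocytes, and TTN, which encodes the giant sarcomere spring protein, was listed at 0 at D15 and in cardiomyocytes after 203 FPKM at D10, so no fold is given for it. Of 18 calcium handling and ion channel genes, 16 were higher and 0 lower (median 3.33), including RYR2, the calcium release channel (1.41 against 75.9), and SLC8A1, the sodium-calcium exchanger (2.01 against 376). Of 20 genes of mitochondrial and fatty acid metabolism, 10 were higher and 0 lower (median 1.00), including CKM, muscle creatine kinase (0.430 against 176), and PPARGC1A (1.53 against 41.2), a coactivator of mitochondrial biogenesis. FABP3 stood at 409 in hESC and 395 in cardiomyocytes, with a low of 8.02 at D3. The medians of the sarcomere and calcium lists lay above all of the 10000 random lists matched on expression (percentile 100), and that of the metabolic list lay at percentile 99.9.

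Pluripotency and cell division genes went the other way. Of 21 pluripotency genes, 19 were 2-fold lower and 0 higher in cardiomyocytes (median log2 change -3.80, percentile 0), and of 28 proliferation genes, 19 were lower and 1 higher (median -1.83, percentile 0). AURKB stood at 107 FPKM in hESC and 11.2 in cardiomyocytes, CCNB1 at 145 and 20.1, and TYMS, the exception, at 8.80 and 36.2. Of 17 DNA methylation genes, 5 were higher and 2 lower (median 0.37). The de novo methyltransferase DNMT3B stood at 126 and 6.10, while the demethylating enzyme TET2 stood at 2.86 and 22.9. Of 15 Polycomb genes, 4 were higher and 4 lower (median -0.18), with PHC1 at 408 in hESC and 22.8 in cardiomyocytes. Of 14 imprinted genes, 7 were higher and 5 lower (median 0.37, and -0.32 without the filter on low values). IGF2 stood at 0.821 and 705, next to H19 on the same chromosome arm.

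**Figure D1:**
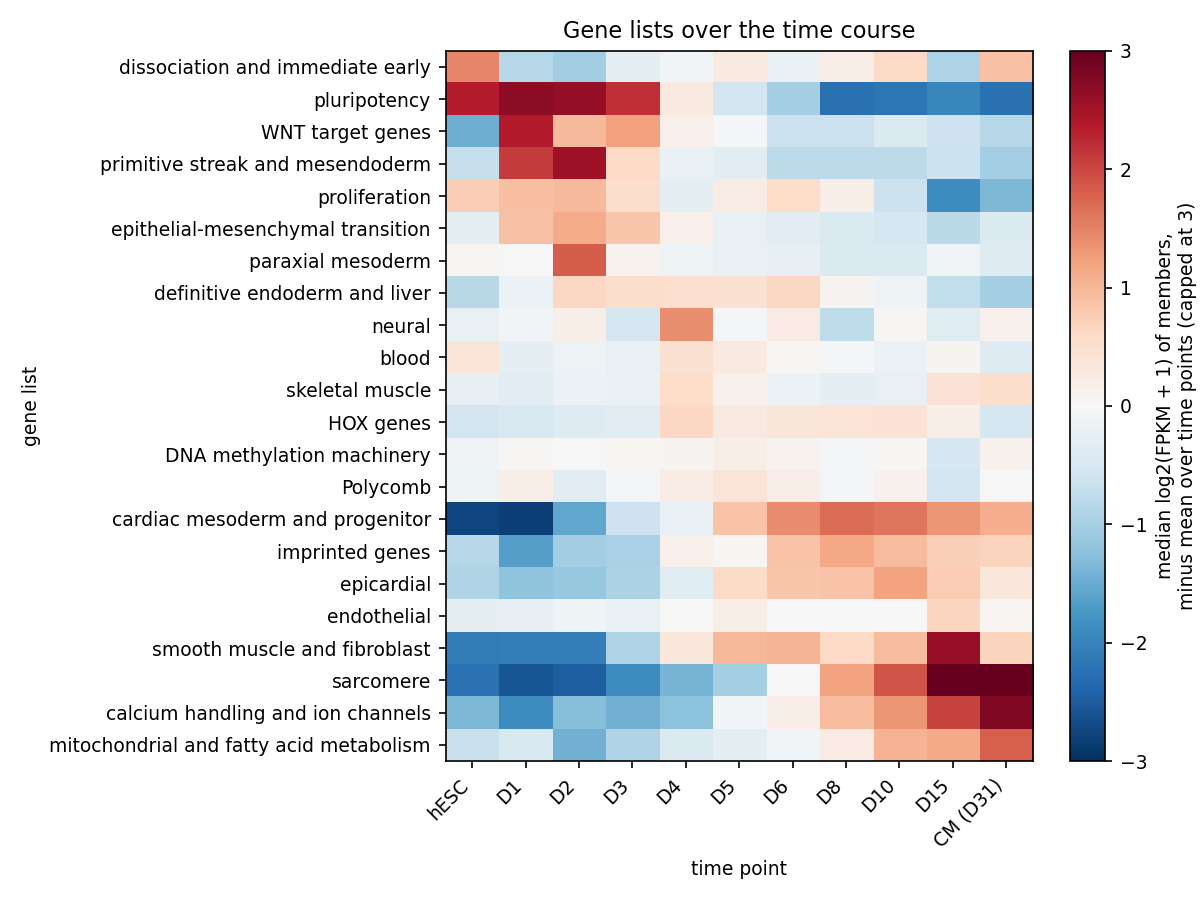
Median log2(FPKM + 1) of the members of 22 fixed gene lists (vertical axis) at 11 time points (horizontal axis), after subtracting each list's mean over time points; red is above and blue below that mean, capped at 3. Pluripotency is high from hESC to D3, primitive streak genes at D1 and D2, WNT target genes from D1 to D3, and sarcomere and calcium handling genes from D8 on; the difference of 2 list medians is not the median change of the members.

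**Figure D2:**
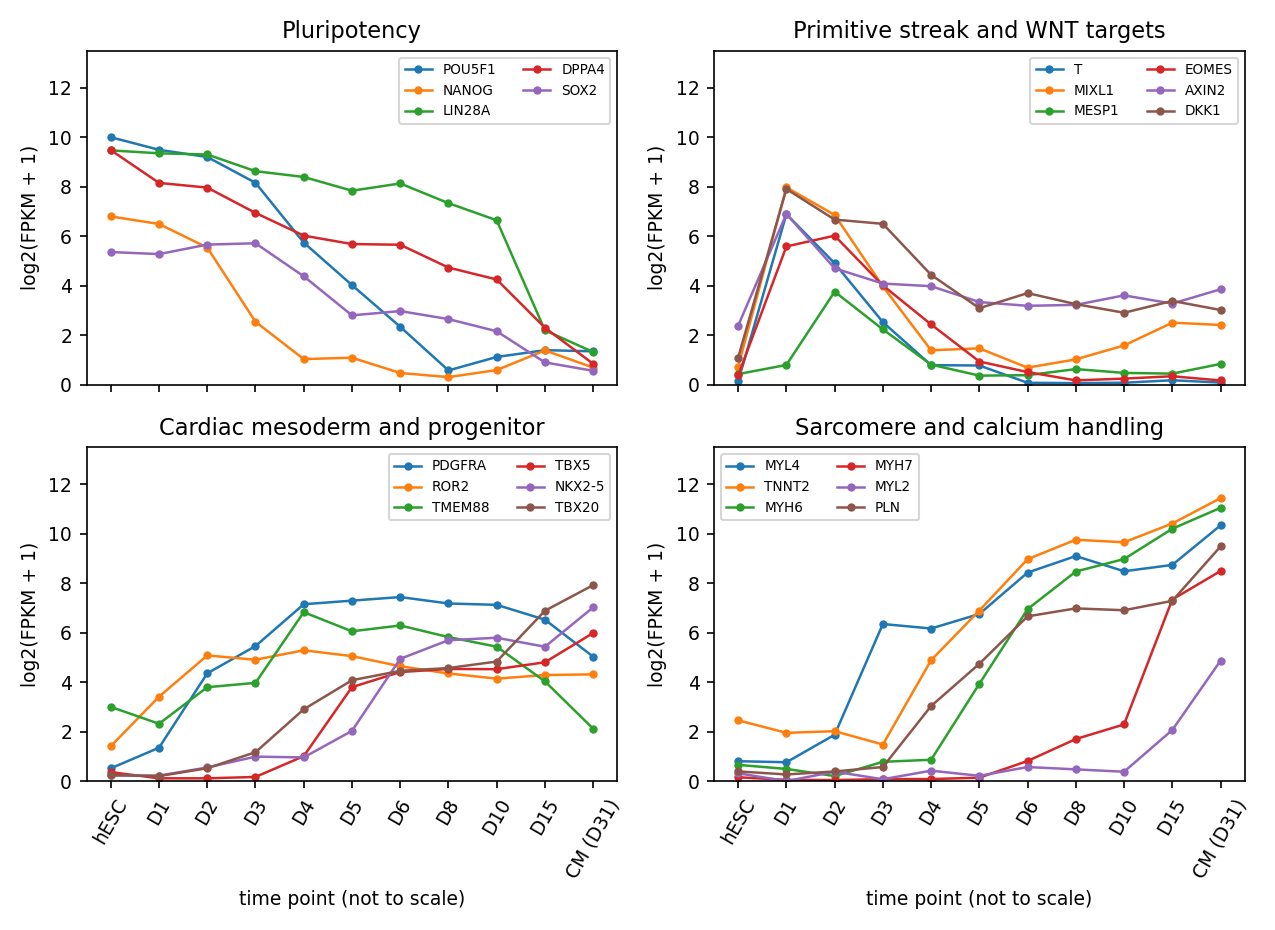
Values of 23 genes of the fixed lists, as log2(FPKM + 1), at 11 time points that are not drawn to scale in time; each point is the authors' single value of a time point. POU5F1 declines from 1026 to 1.54 FPKM while MIXL1 peaks at 251 FPKM at D1 and TNNT2 reaches 2785 FPKM in cardiomyocytes.

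The first step, from hESC to D1, covers 24 hours of GSK3 inhibition. Mesendoderm genes and WNT targets were higher at D1. MIXL1 stood at 0.654 FPKM in hESC and 251 at D1, NODAL at 0.472 and 201, T (brachyury) at 0.0936 and 118, and EOMES at 0.290 and 47.0. Among WNT targets, SP5 stood at 0.162 and 133, AXIN2, a negative feedback gene of the pathway, at 4.22 and 118, DKK1 at 1.13 and 239, and CDX1 at 0.253 and 98.4. Of 16 primitive streak genes, 12 were 2-fold higher and 0 lower (median log2 change 2.73), and of 17 WNT target genes, 13 were higher and 0 lower (median 3.97), both at percentile 100. Pluripotency genes split, with 5 higher and 7 lower: POU5F1 stood at 720 and NANOG at 89.2 at D1, ZFP42 at 21.4 in hESC and 104 at D1, and DPPA4 at 714 and 284.

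The hESC column also stood apart in stress and immediate early genes at the same step. All 13 measured members of that list were at least 2-fold lower at D1 (median -2.41, percentile 0), including HSPA1B, a heat shock chaperone (222 against 22.9 FPKM), and ATF3 (146 against 17.1). The largest decreases by rule were in the small nucleolar RNAs SNORA31 (1232 against 18.96) and SNORA14B (414 against 6.44) and in DUSP2 (88.3 against 0.647), followed among protein-coding genes by DDIT3, a transcription factor of the integrated stress response (682 against 13.6), and GDF15 (94.3 against 1.06). RNA composition differed too: of 16 genes of that list 1 was higher and 7 lower at D1 (median -0.46, percentile 2.78). Of 105 small nucleolar RNAs 8 were higher and 63 lower. This step had 2599 genes higher and 2407 lower, more than any other step between neighbouring time points. With a pseudocount of 0.1 the counts were 3837 higher and 4564 lower, so the balance turned.

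**Figure D3:**
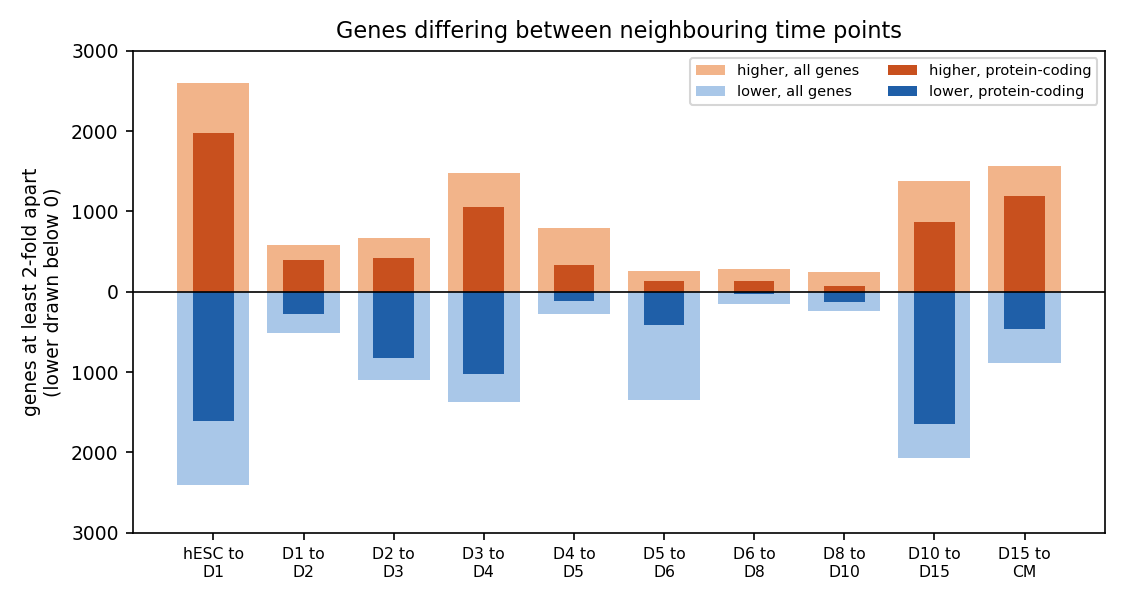
Number of genes at least 2-fold higher (above 0) or lower (drawn below 0) in log2(FPKM + 1) at each step between neighbouring time points, for all kept genes (wide bars) and protein-coding genes (narrow bars). The steps from hESC to D1, D3 to D4, D10 to D15 and D15 to cardiomyocytes (CM) hold the most genes, and those from D6 to D8 and D8 to D10 the fewest.

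From D1 to D2 mesoderm genes were higher, and by D3 streak and paraxial mesoderm genes were lower. At D2, APLNR, the apelin receptor of early mesoderm, stood at 179.8 FPKM against 6.70 at D1, MESP1 at 12.5 against 0.733, CER1 at 85.7 against 7.68, and DLL3 at 70.0 against 5.05, while NODAL stood at 21.6 against 201 and CDX1 at 10.4 against 98.4. The primitive streak list split, with 6 of 16 genes higher and 5 lower at D2 than at D1. Its median was above 0 (0.50, percentile 100), and 9 of its 15 genes of at least 5 FPKM peaked at D2. Of 21 cardiac mesoderm genes, 11 were higher and 0 lower at D2 than at D1 (median 1.06, percentile 100). They include PDGFRA (19.5 at D2 against 1.55 at D1), HAND1 (9.47 against 0.174) and ROR2 (32.9 against 9.66). Of 11 paraxial mesoderm genes, 6 were higher (median 1.42), and of 15 genes of epithelial-mesenchymal transition 6 were higher and 3 lower, with SNAI2 at 0.568 and 13.3 and the epithelial cadherin CDH1 at 69.6 and 23.9. By D3, 14 of 16 primitive streak genes were lower than at D2 (median -1.97, percentile 0), T standing at 4.76 and MIXL1 at 14.7, and NANOG at 4.81 against 45.5. Of 11 paraxial mesoderm genes 7 were lower and 0 higher (median -1.30, percentile 0). Among protein-coding genes outside the set of jumping genes, MYL4 was the largest increase of that step (2.66 at D2 and 80.8 at D3). It was followed by the testis histone HIST1H1T (6.85 and 132.5) and the smooth muscle actin ACTA2 (0.856 and 29.4). HIST1H1T was back at 3.67 at D4, a reversal that the rule for jumping genes does not catch. CYP26A1, a retinoic acid hydroxylase, was the largest decrease (29.9 at D2 and 1.23 at D3). By size alone TUBB3 (0.0848 at D1 and 190.3 at D2) and NDUFA7 were among the largest increases from D1 to D2. PSMA1 (194 and 0.884), SDHD and NDUFB8 were the largest decreases, but each gene of both sets was back near its D1 value at D3. The counts were 577 higher and 508 lower from D1 to D2, and 672 and 1095 from D2 to D3. With a pseudocount of 0.1 they were 1590 and 1383, then 2237 and 1866, so the balance of the D3 step turned.

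From D3 to D4 some stromal and HOX genes and the imprinted neighbours H19 and IGF2 were higher, and cell division genes were lower. The collagen COL3A1 stood at 2.07 FPKM at D3 and 78.7 at D4, LUM at 1.38 and 47.4, H19 at 3.30 and 222, IGF2 at 1.52 and 42.9, and HOXB1 at 2.47 and 15.7. Of 15 smooth muscle and fibroblast genes, 6 were higher and 1 lower (median 0.90), of 18 HOX genes 6 were higher and 0 lower (median 0.83), and of 21 cardiac mesoderm genes 8 were higher and 0 lower (median 0.84), at percentiles of 99.99 to 100. TMEM88, a WNT inhibitor of cardiac progenitors, stood at 14.7 and 113. Of 21 pluripotency genes, 12 were lower and 0 higher (median -1.33), with POU5F1 at 285 and 52.5. Of 28 proliferation genes, 14 were lower and 0 higher (median -0.96), with PCNA at 179 and 64.2. Of 14 imprinted genes, 3 were higher and 0 lower. In the same column RNA composition differed: of the 16 genes of that list 2 were higher and 5 lower than at D3 (median -0.68, percentile 5.7). That list includes histone genes, so it is not independent of the lower cell division genes. Of 105 small nucleolar RNAs 12 were higher and 35 lower than at D3. At D5 against D4, 9 of the 16 were higher and 0 lower (median 1.04, percentile 100). The proliferation list did not stay low either. Its median level in log2(FPKM + 1) was 5.89 at D3, 5.08 at D4, 5.60 at D5 and 5.92 at D6. From D3 to D4, TUBB3, SNORA79 and H19 led the increases by size alone, and PSMA1, NDUFB8 and SDHD the decreases. Of these, only H19 does not jump between columns. In all, 1475 genes were higher and 1368 lower (3167 and 2205 with a pseudocount of 0.1), but 1377 and 1472 after rescaling, so the balance turned.

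From D4 to D6 some cardiac transcription factors and contractile genes were higher. TBX5 stood at 1.01 FPKM at D4, 12.9 at D5 and 20.3 at D6, NKX2-5 at 0.944, 3.09 and 29.8, MEF2C at 2.55, 14.1 and 45.2, and MYH6 at 0.819, 14.3 and 123. Of 27 sarcomere genes, 9 were higher and 0 lower at D5 than at D4 (median 0.51), and 8 and 0 at D6 against D5 (median 0.76), both at percentile 100. Of 21 cardiac mesoderm genes, 7 were higher and 1 lower at D5 (median 0.19, percentile 94.5), and 5 and 0 at D6 (median 0.61). At D5, 799 genes were higher and 273 lower than at D4, and at D6, 263 were higher and 1343 lower than at D5, but among protein-coding genes these counts were 338 and 117, then 140 and 411. With a pseudocount of 0.1 and all genes they were 2018 and 903, then 599 and 3667. The D5 column had the highest small RNA share of summed FPKM (38.8%, against 27.3% at D4 and 32.8% at D6). Its approximate depth was 0.599 relative to D1, against 0.909 at D4.

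From D6 to D10 few genes differed between neighbouring time points. The step from D6 to D8 had 289 genes higher and 147 lower, that from D8 to D10 251 and 242 (1159 and 542, then 1131 and 603, with a pseudocount of 0.1). Among protein-coding genes the counts were 131 and 34, then 73 and 122, so the balance of the D10 step turned, as it did with rescaling and with genes above 0 in both columns. The r across protein-coding genes was 0.986 and 0.981. Of 27 sarcomere genes, 13 were higher and 0 lower at D8 than at D6 (median 0.89, percentile 100), with MYL3 at 8.19 and 72.7 and MYOM1 at 2.36 and 15.3, and 2 were higher and 0 lower at D10 than at D8. NPPA, the atrial natriuretic peptide gene, stood at 9.06 at D6, 38.2 at D8 and 95.9 at D10. At D10, CKM (25.6 against 7.05 at D8) and IGFN1 (9.16 against 0.691) were among the largest increases. Of 28 proliferation genes, 5 were lower and 0 higher at D10 than at D8 (median -0.83, percentile 0).

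From D10 to D15 late contractile genes were higher and cell division genes lower. MYH7, the beta heavy chain of cardiac myosin, stood at 3.90 FPKM at D10 and 161 at D15, the largest increase of the step among protein-coding genes that do not jump between columns, and the collagen cross-linking enzyme LOX at 1.62 and 71.1. LIN28A, at 3.57 FPKM at D15, was the largest decrease among these genes. Of 27 sarcomere genes, 16 were higher and 1 lower (TTN, listed at 0), and of 18 calcium and channel genes 9 were higher and 1 lower. Of 15 smooth muscle and fibroblast genes 7 were higher and 0 lower, with COL3A1 at 529 and 2037. FN1 of the transition list stood at 762 and 2880, but of the 15 genes of that list only 3 were higher and 1 lower (median -0.41). Of 28 proliferation genes, 21 were lower and 0 higher (median -1.38), and of 13 immediate early genes 7 were lower and 0 higher (median -1.44), both at percentile 0. The counts were 1373 higher and 2066 lower, but 3234 and 2910 with a pseudocount of 0.1, so the balance turned. RNA composition genes went both ways in this step, with 5 of 16 genes of that list higher and 6 lower. Their median (-0.79) lay at percentile 51.9, near the middle of the matched lists. MIR4313, a microRNA entry at 0.245 FPKM at D10 and 7911 at D15, was back at 0.256 in cardiomyocytes.

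The last step, from unpurified D15 cells to Percoll-purified cardiomyocytes, joined higher contractile genes to lower stromal genes. It spans both the time from D15 to day 31 and the purification, and no group was profiled that would tell these apart. TNNI1 stood at 370 FPKM at D15 and 1038 in cardiomyocytes, ACTC1 at 827 and 2202, CSRP3 at 57.3 and 211, and MYL2, the ventricular light chain, at 3.19 and 28.2. COL1A1 stood at 733 and 224, COL3A1 at 2037 and 609, LUM at 108 and 16.6, and GPC3 at 656 and 66.4. Of 27 sarcomere genes, 17 were higher and 0 lower (median 1.15, percentile 100), and of 15 smooth muscle and fibroblast genes 1 was higher and 8 lower (median -1.04, percentile 0). Of 10 endothelial genes 0 were higher and 4 lower (median -0.82), and of 18 HOX genes 0 were higher and 5 lower (median -0.79). Most genes of these lists had low values, with 2 endothelial and 5 HOX genes reaching 5 FPKM at any time point. By the approximate depth, low values are least precise at D15. Immediate early genes differed in the same step: 12 of 13 were higher in cardiomyocytes (median 2.01, percentile 100), with ATF3 at 6.09 and 158 and EGR1 at 20.3 and 203, and NR4A1 and NR4A3 next to ATF3 among the largest increases. In all, 1570 genes were higher and 883 lower; the median of all kept genes was 0.12 on the log2 scale (0.06 after rescaling), and rescaling moved the higher share from 64.0% to 55.4%. With a pseudocount of 0.1 the counts were 2435 higher and 2690 lower, so the balance turned.

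Lists of other cell types were followed over the same ends. Between hESC and cardiomyocytes, 12 of 15 smooth muscle and fibroblast genes were higher and 1 lower (median 2.18), with the members ACTA2, TAGLN and CNN1 also known from immature cardiac muscle and COL3A1 at 609 FPKM in cardiomyocytes, and 6 of 9 epicardial genes were higher (median 1.24), with TBX18 at 0.173 and 6.14 FPKM. Of 14 endoderm and liver genes 2 were higher and 1 lower (median -0.07), AFP standing at 0.997 in hESC, 26.6 at D8 and 16.1 in cardiomyocytes. Of 11 paraxial mesoderm genes 1 was higher and 4 lower (median -0.36), of 10 endothelial genes 1 and 1 (median -0.13), of 8 neural genes 3 and 2 (median 0.21, and -0.05 without the filter), and of 8 blood genes 0 and 3 (median -0.52). The 3 higher neural genes include TUBB3, which alternates between columns, so its difference is uncertain. Among 3 measured skeletal muscle genes 0 were higher or lower. Of 16 primitive streak genes 1 was higher and 2 lower (median -0.23), of 17 WNT targets 5 and 2 (median 0.20), and of 21 cardiac mesoderm genes 17 and 1 (median 3.72, KDR the lower gene). Of 15 transition genes 7 and 5 (median 0.86), of 18 HOX genes 3 and 0 (median 0.11, and -0.05 without the filter), of 13 immediate early genes 5 and 3 (median 0.11), and of 16 RNA composition genes 5 and 10 (median -1.30). The RNA component of the signal recognition particle, RN7SL1, stood at 74763 FPKM in hESC and 23240 in cardiomyocytes.

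The D3 sort asks what distinguishes the ROR2-positive cells, called PMESO, from the ROR2-negative cells of the same day. In the authors' deposited table the sort marker ROR2 (hg19 chromosome 9, 94325373 to 94712444) stood at 5.90 FPKM in negative and 72.0 in PMESO cells, a 12.2-fold difference, and PDGFRA (chromosome 4, 54243810 to 55164414, a span merged with neighbouring genes) at 6.80 and 91.9, both with q = 0.000375, the smallest of the table. The largest increases in the authors' deposited table included APLNR (2.21 against 119 FPKM), BMPER, a BMP-binding protein (3.64 against 146), the matrix genes HAPLN1 (5.85 against 212) and HAS2 (3.31 against 103), CER1 (1.16 against 62.7), HTRA1 and COLEC12. GYPB was also among the 10 largest in the authors' deposited table, but it has a close homologue, so its value is uncertain. The largest decreases in the authors' deposited table were in C9orf135 (65.7 against 2.80), HPGD, a prostaglandin dehydrogenase (68.1 against 3.96), RP11-267L5.1, LINC00678, MGAT4C, TRIML2, RP11-1144P22.1, SOX2 (58.4 against 6.73), GAP43 and CLU. The authors' deposited table as used here held 4648 genes, 2567 higher and 2081 lower in PMESO, and 790 of the higher and 518 of the lower genes passed the 2-fold limit on log2(FPKM + 1), against 1200.0 and 992 by the ratio in the authors' deposited table.

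Of 16 lists tested in the D3 sort of the authors' deposited table, 5 passed the adjustment. In the authors' deposited table, 18 of 18 called cardiac mesoderm genes were higher in PMESO (Fisher's exact adjusted p = 0.000422 over 16 lists, and 0.000522 without the sort marker ROR2), with GATA6 at 1.76 and 41.2 FPKM, HAND1 at 1.92 and 47.5 and GATA4 at 2.25 and 24.9. All 16 called primitive streak genes were higher in the authors' deposited table (adjusted p = 0.000672), with MESP1 at 0.262 and 5.79 and MIXL1 at 1.75 and 33.9. So were 9 of 9 WNT targets (adjusted p = 0.0175), led by LGR5 at 1.03 and 43.7, and 11 of 11 endoderm genes (adjusted p = 0.00635), with SOX17 at 0.664 and 12.5 and FOXA2 at 1.15 and 9.40, in the authors' deposited table; CER1 and FOXA2 count in both the streak and the endoderm list. Of 16 called pluripotency genes in the authors' deposited table, 15 were lower (adjusted p = 0.000422), with POU5F1 at 449 and 87.3 and NANOG at 2.19 in PMESO cells. The transition list split, 10 higher and 4 lower in the authors' deposited table (adjusted p = 0.572), with SNAI2 (0.553 against 12.2) and VIM (426 against 1396) higher and CDH1 (58.8 against 13.6) lower.

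Further lists in the authors' deposited table did not pass the adjustment at D3. Of the called genes there, 7 sarcomere genes were higher and 2 lower (adjusted p = 0.459), with MYL4 at 6.33 and 152 FPKM but ACTC1 at 142 and 82.1 and TPM1 at 289 and 187. In the authors' deposited table, 5 proliferation genes were higher and 4 lower, 5 immediate early genes higher and 5 lower, 7 smooth muscle and fibroblast genes higher and 3 lower, 4 HOX genes higher and 1 lower, and 2 neural genes higher and 4 lower. Calcium and channel genes were 4 and 2, DNA methylation genes 6 and 1, Polycomb genes 4 and 2, and imprinted genes 4 and 1 in the authors' deposited table. Lists with under 5 called genes were not tested: paraxial mesoderm 4 and 0, metabolism 1 and 2, endothelial 1 and 2, blood 2 and 0, and RNA composition 2 and 2, while the epicardial and skeletal muscle lists had 0 called genes in the authors' deposited table.

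The D4 sort compares ROR2-positive cells with and without PDGFRa, the positive cells being called CMESO. In the authors' deposited table PDGFRA stood at 8.28 FPKM in negative and 304 in CMESO cells, a 36.7-fold difference, with q = 0.000269, the smallest of the table. ROR2 has no entry in the D4 table as used here, which holds only genes with a q-value under 0.05, so its difference is not known. Besides PDGFRA, the largest increases in the authors' deposited table were in HAPLN1 (5.69 against 280.1), COL3A1 (1.08 against 76.8), HTRA1, RGS4 (1.21 against 70.2), MYL4 (12.2 against 423), KDR, a VEGF receptor (4.18 against 163), the guanylate cyclase subunit GUCY1A3, AFAP1L2 and MYOCD, a coactivator of muscle genes (1.37 against 54.2). The largest decreases in the authors' deposited table were in GALNT14 (27.6 against 0.846), GRHL2 and TFAP2A, both transcription factors (19.6 against 0.719 and 10.4 against 0.237), the epithelial cadherin CDH1 (41.9 against 3.90), FZD5, SOX2 (13.7 against 0.529), the BMP antagonist GREM1 (22.7 against 1.48), CAPN13, HPGD and HLA-B. The authors' deposited table as used here held 4825 genes, 2291 higher and 2534 lower in CMESO, of which 753 and 619 passed the 2-fold limit on log2(FPKM + 1), against 1104 and 1093 by the ratio in the authors' deposited table.

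**Figure D4:**
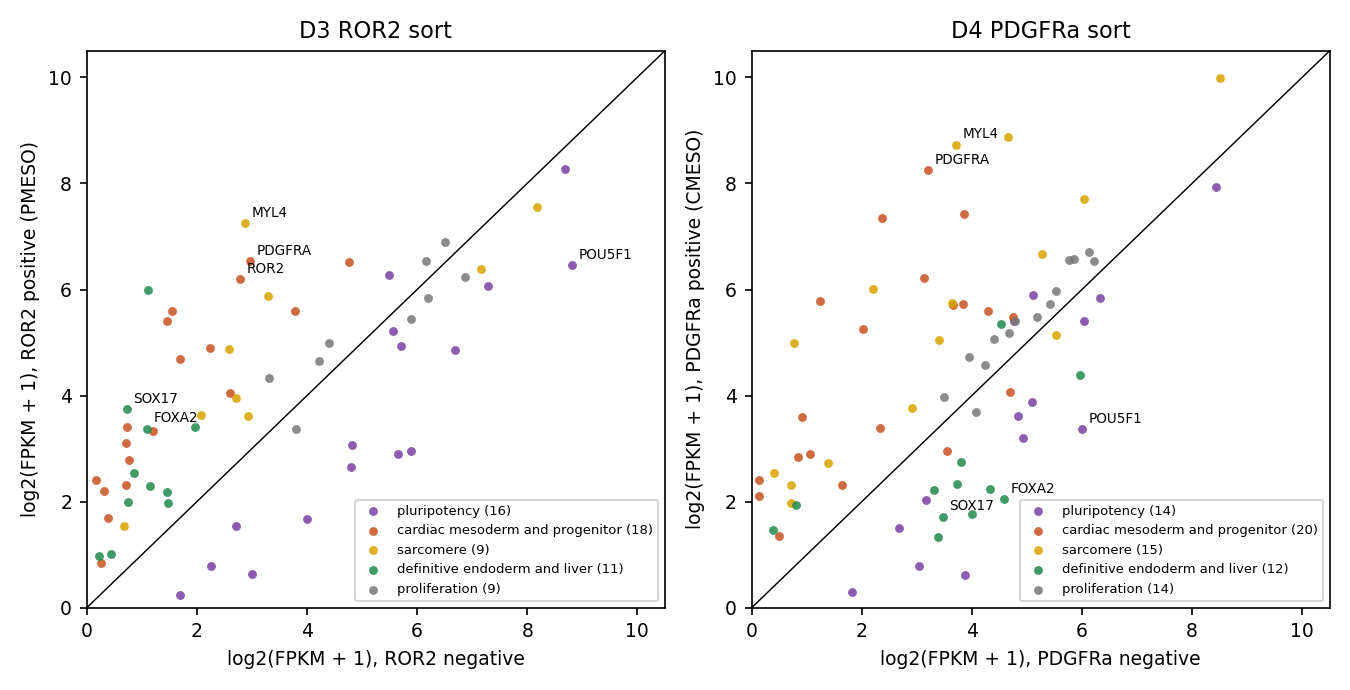
Authors' FPKM values, as log2(FPKM + 1), of called genes of 5 fixed lists in the negative (horizontal) and positive (vertical) population of the D3 sort (left) and the D4 sort (right); points above the diagonal are higher in the positive cells, and numbers in brackets are genes. Endoderm genes lie above the diagonal at D3 (11 of 11) and mostly below it at D4 (9 of 12).

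CMESO cells were richer in contractile and dividing-cell transcripts. In the authors' deposited table, 14 of 15 called sarcomere genes were higher (Fisher's exact adjusted p = 0.00305 over 20 lists), with MYL7 at 24.3 and 469 FPKM, TNNT2 at 3.60 and 63.3 and TNNI1 at 0.697 and 30.6, and TNNC1 lower. Cardiac mesoderm genes were 18 higher and 2 lower in the authors' deposited table (adjusted p = 0.00263, and 17 and 2 without the sort marker PDGFRA, adjusted p = 0.00305), TBX20 standing at 3.09 and 37.0 and TMEM88 at 13.4 and 172, with ISL1 (24.9 against 15.8) and FOXC1 the lower genes. Calcium and channel genes were 10 higher and 1 lower (adjusted p = 0.0178), smooth muscle and fibroblast genes 11 and 1 (adjusted p = 0.0114), and proliferation genes 13 and 1 (adjusted p = 0.00400) in the authors' deposited table. The proliferation differences were small, 0 of them reaching 2-fold, with CDK1 at 53.6 and 93.1 in the authors' deposited table. Pluripotency genes were 2 higher and 12 lower in the authors' deposited table (adjusted p = 0.0478), with POU5F1 at 63.3 and 9.30. Immediate early genes, which react to cell handling, were 7 higher and 1 lower in the authors' deposited table (adjusted p = 0.0889), with FOS at 165 and 333.

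The remaining lists of the D4 sort did not pass the adjustment. Endoderm genes were 3 higher and 9 lower in the authors' deposited table (adjusted p = 0.337), with FOXA2 at 23.0 and 3.16 FPKM and SOX17 at 10.1 and 2.30. The transition list was 9 higher and 6 lower in the authors' deposited table (adjusted p = 0.585), with VIM at 158 and 1986 and EPCAM at 134 and 19.6. In the authors' deposited table primitive streak genes were 3 and 4, WNT targets 3 and 3, DNA methylation genes 3 and 2, Polycomb genes 5 and 1, paraxial mesoderm genes 1 and 4, neural genes 1 and 4, endothelial genes 4 and 1, HOX genes 4 and 3, imprinted genes 5 and 3, metabolic genes 1 and 4, and RNA composition genes 7 and 3, each pair given as higher and lower. Untested in the authors' deposited table for having under 5 called genes were the epicardial list (1 and 1), the blood list (3 and 0) and the skeletal muscle list (0 and 1).

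Both sorts were then set side by side over the 2160 genes held in both of the authors' deposited tables. Of these, 923 were higher and 703 lower in both positive populations, so 75.3% had the same direction, where 50.2% would if directions were independent (odds ratio 10.2, Fisher's exact p = 6.04e-131 over genes that are not independent). Cardiac mesoderm genes were higher in both of the authors' deposited tables for 15 of 17 genes, and 10 of 11 pluripotency genes were lower in both. Endoderm genes turned: 8 of the 10 held in both of the authors' deposited tables were higher in PMESO and lower in CMESO than in the negative cells of their sort, against 356 of all 2160 genes (odds ratio 20.7, Fisher's exact p = 1.68e-05, adjusted p = 0.000219 over 13 lists). The same test gave an adjusted p of 0.109 for the primitive streak list in the authors' deposited tables, with 4 of 7 genes. The genes compared with include those lower in PMESO, which could not turn this way. Both lists had 0 genes lower in PMESO here, so these tests partly restate the D3 direction. Among all genes higher in PMESO in the authors' deposited tables, 356 were lower and 923 higher in CMESO, against 8 and 2 endoderm genes. That narrower comparison was not tested. The negative cells differ between the sorts, since those of D4 were gated as ROR2-positive, and a gene held in only 1 table was left out.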

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

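The tests on protein-coding genes, on genes above 0 in both columns, without the alternating genes, without hESC, D15 and cardiomyocytes, with D1 or D10 as an end point, without the sort marker and with other limits on fold or q-value were chosen after the values were seen. No paired analysis was possible because the time-course table gives 1 value per group and the sort tables give no values per library. For the same reason leaving out a replicate, a replicate block, the limma and camera settings and a rescaling of the sort tables were not run, and DESeq2 was not run for want of counts. The cause was not tested for the differences below, except where fewer genes or time points were counted. By the approximate depth, low values are limited most at D15, D5 and in hESC, with the D15 estimate resting on the fewest genes.

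With a pseudocount of 0.1 in place of 1, which counts changes among low values, higher and lower genes numbered 3837 and 4564 at D1 against hESC. Higher and lower genes numbered 1590 and 1383 at D2 against D1, 2237 and 1866 at D3 against D2, 3167 and 2205 at D4 against D3, 2018 and 903 at D5 against D4, and 599 and 3667 at D6 against D5. They numbered 1159 and 542 at D8 against D6, 1131 and 603 at D10 against D8, and 2435 and 2690 in cardiomyocytes against D15. They numbered 3234 and 2910 at D15 against D10, and lower genes 778 in the D3 sort and 950 in the D4 sort. The balance of higher and lower genes turned at 4 steps: D1, D3, D15 and cardiomyocytes, each against the time point before. Median log2 changes of lists between hESC and cardiomyocytes were -5.19 for pluripotency, -0.91 for primitive streak, 5.48 for cardiac mesoderm, 8.06 for sarcomere, 4.47 for calcium handling, -1.18 for paraxial mesoderm, 2.89 for smooth muscle and fibroblast, 2.23 for epicardial and -1.60 for blood genes. Each of these medians kept its direction. Of 80 values of named genes at single steps (some genes recur), 50 differed by more than 1.5-fold under this setting.

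With protein-coding genes only, there were 283 lower genes at D2, 422 higher at D3, 338 higher and 117 lower at D5, 140 and 411 at D6, 131 and 34 at D8, and 73 and 122 at D10, each against the time point before. There were 873 higher at D15 against D10 and 468 lower in cardiomyocytes against D15. With only genes above 0 in both columns, 157 were lower at D5, 190 higher and 56 lower at D8, and 140 higher and 154 lower at D10. Without a fold limit the D3 sort had 2567 higher and 2081 lower genes and the D4 sort 2291 and 2534, where the balance turned. With the limit on the authors' ratio they had 1200.0 and 992, then 1104 and 1093. Without hESC, D15 and cardiomyocytes, 11868 genes in place of 18390 differed over the time course, since fewer columns were compared. Without the filter the median of the imprinted list was -0.32 in place of 0.37, and the neural (-0.05), HOX (-0.05) and skeletal muscle (-0.03) medians turned too, with more members counted.

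Rescaling by median-of-ratios factors left 23 counts, 23 list medians and 80 values of named genes at single steps within 1.5-fold, but turned the balance at D4 against D3 (1377 higher, 1472 lower), at D10 against D8 (241 and 250.0) and in cardiomyocytes against hESC (3815 and 3879). With D10 in place of cardiomyocytes the last balance turned too (2906 and 2969). Leaving out the alternating genes left 23 counts within 1.5-fold, but these 35 genes are too few to move any count past that limit. A q-value under 0.01 left 4 counts within 1.5-fold. The filter cannot alter the counts of higher and lower genes by construction, since a gene under 1 FPKM throughout cannot reach the 2-fold limit. Without the sort marker the cardiac mesoderm list kept its direction in both sorts.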

Other observations

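The tests of the scale of the D15 column, of MT-RNR1 and of the D3 mixture were chosen only after the results were seen, and so were the gene families of the next paragraph.

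Metallothioneins, which bind zinc and copper and respond to metals and glucocorticoids, were high at D4: of 9 genes measured, 8 were higher and 0 lower at D4 than at D3, and 0 higher and 8 lower at D5 than at D4. MT1E stood at 0.623 FPKM at D3, 53.2 at D4 and 0.317 at D6, MT2A at 0.854, 49.9 and 6.98 from D3 to D5, and MT1G at 2.20, 85.2 and 5.35. Replication-dependent histone genes, whose RNA peaks in S phase, were low in the same column: of 65 genes named as histone cluster genes, 0 were higher and 63 lower at D4 than at D3, and 57 higher and 0 lower at D5 than at D4. HIST1H3F stood at 889 at D3 and 60.5 at D4, HIST1H1D at 1243 and 116, and HIST1H1B at 1103 and 110.5, and HIST1H3B stood at 123 at D4 and 689 at D5. Most of these RNAs lack a poly(A) tail, and the libraries were made from total RNA. Among the proliferation genes 14 of 28 were lower and 0 higher at D4 than at D3 (median -0.96). At D5 against D4, 3 of them were higher and 0 lower (median 0.65, percentile 100). RNA composition differed in the same column: of 105 small nucleolar RNAs 35 were lower and 12 higher at D4 than at D3.

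Some genes alternate between columns: 35 genes, 28 of them protein-coding, are high in the D2, D4, D6, D10 and cardiomyocyte columns and low in the others, or the reverse, a division found by scanning 1012 splits of the 11 columns. Of the protein-coding ones, 25 of 28 (89.3%) share same-strand exon sequence with another gene, against 2297 of 14518 others (15.8%, odds ratio 44.3, Fisher's exact p = 2.14e-17). A change of the proteasome and respiratory complexes that PSMA1, PSMA2, SDHD, NDUFB8 and NDUFA7 belong to is argued against by the other 50 subunits, whose median absolute difference between the column sets was 0.10 on the log2 scale (at most 0.40), where these 5 had 5.12. TUBB3 stood at 0.0433 FPKM in unsorted D3 cells, but at 214 and 133 in the negative and positive D3 populations of the authors' deposited table. A candidate explanation is that reads of overlapping genes were assigned to 1 or the other gene in different runs of the software, and single-gene values of such genes in single columns would then not measure expression.

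Mitochondrial messenger RNAs were higher at D15 and in cardiomyocytes than at D10: the 13 had a median log2 change of 2.76 at D15 (2.12 to 3.62) and 3.12 in cardiomyocytes, with MT-CO1 at 1563 FPKM at D10 and 10121 at D15. A change of scale of the whole D15 column is argued against by nuclear genes, whose median was -0.0440. The ribosomal MT-RNR1 stood at 18389 FPKM at D10 and is listed at 0 at D15 and in cardiomyocytes, but its loss cannot supply the whole gain, which was 2.03 times as large in FPKM times length. A larger respiratory chain in the cells cannot be told apart from other explanations at D15. The median log2 change of 63 nuclear subunit genes was -0.62 (0 were 2-fold higher, 10 lower), which goes against it. This median however lay at percentile 69.7 of lists matched on expression. In cardiomyocytes against D10 the nuclear subunit genes had a median of 0.29 (percentile 100), and MT-RNR1 at 0 in the same 2 columns leaves a different handling of mitochondrial reads open.

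Unsorted D3 values lay between those of the sorted D3 populations of the authors' deposited table for 977 of 1128 genes (86.6%), where the next time point, D2, had 60.02%. This ranking cannot tell a mixture of both populations from mere likeness of cells of the same day. If the unsorted D3 cells were a mixture, the PMESO share would be 40.2% by the median gene. The shares from genes higher (33.7%) and genes lower (52.7%) in PMESO differed. At D4 the same comparison gave 882 of 1153 genes (76.5%), against 69.0% at D5, and a CMESO share of 52.4%, with 34.3% and 87.8% from higher and lower genes, although ROR2-negative cells were in neither sorted population. The tables were normalized apart, so the shares are approximate, and a gate loss during sorting was not tested.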
